A study of Eisenia fetida with 6 samples.

How the data were processed

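The data are RNA-seq measurements of intestinal tissue from the earthworm Eisenia fetida in 2 groups, a control group and a group exposed to tri-n-butyl phosphate (TnBP) at 10 mg/kg, with 3 libraries each. Groups were taken from the treatment labels. Per the labels' protocols, each library was made from the pooled intestines of 3 worms, RNA was extracted with Trizol, and libraries followed a BGI protocol. The labels do not say whether the pools of a group came from separate soil containers, so p-values measure the spread between pools of worms, which may share a container. The labels give no sequencing or library batch, and a batch that followed the groups could not be told apart from treatment.

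Each library has 1 deposited table with a gene identifier, a length in bases, an expected count and an FPKM value, per the file headers. The deposited expected counts are not whole numbers throughout and are not normalized. The deposited FPKM values were scaled by the authors for gene length and sequencing depth, per the file headers. RSEM and Bowtie 0.12.2 are named in the submitters' processing notes, without their role or settings. The same notes name mm8, a mouse genome build, whereas every identifier in the tables carries an Eisenia fetida suffix and is an assembled sequence. The assembler, the read filters and whether counting used strand are not given in the sources used here. Each table lists only sequences with a value above 0, and a sequence missing from a table was set to 0 for that library. Identifiers take 2 forms, a CL number followed by a contig number, or a single unigene number. Sequences that share a CL number were treated as members of 1 assembly cluster, a reading that the files do not spell out. All sequences are called contigs here. RSEM can divide reads between similar contigs of a cluster, so values of single cluster members are uncertain.

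The files do not pair identifiers with gene names or sequences, and no reference was used here. The 16 gene lists fixed in advance (xenobiotic metabolism in 3 phases, antioxidant enzymes, heat shock proteins, metallothionein, digestive enzymes, immunity, junctions, energy metabolism, ribosome, proteasome, lysosome, muscle, nervous tissue and blood pigment) were matched against all 55641 identifiers, and 0 lists had a match. No list could be counted or tested for that reason, and GC content could not be checked.

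Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Contigs were kept with filterByExpr at its minimum count of 10, libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood test with 1 coefficient for treatment over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a contig was called at an adjusted p under 0.05. The fitted change of a contig absent from 1 group depends on edgeR's prior count, so such contigs enter counts by size of change with that fitted value and no fold is given for them. Log2 fold changes are TnBP over control, and standard errors were taken from the fitted change and its F statistic. CPM values were computed here with TMM scaling. TMM moved the median log2 ratio of the tested contigs from 0.79, under library totals, to 0.01, so every fold change is relative to that shift. Values per library were compared by two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 against 3 libraries. Contigs were called present in 1 group only when they passed the test, had under 1 count in every library of the other group and had at least 10 in every library of the first. For clusters, the directions of called members were shuffled 1000 times among all called cluster members. Contigs named in the text were chosen by a rule: the 2 with the largest fitted change in each direction among called contigs with a change of at least 2-fold, no overlap between groups, a mean of at least 10 CPM in the higher group and at least 1 count in every library. These tests, this rule and most alternatives were set before the data were examined. The classes of length and abundance, the summed shares of called contigs, the variation between pools, the comparison of cluster membership, library totals, removal of the length trend and FPKM correlations were chosen after the data had been seen.

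The libraries held 8435554 to 9643939 expected counts, and the median standard error of a log2 fold change was 0.29. Paired libraries of 1 group differed by 2.58 to 3.24 times the chi-square value expected from sampling alone, over contigs with 20 to 5000 counts in the pair, so no library was a copy of another and each counted as 1 replicate. Alternatives were DESeq2 1.42.0, its size factors within edgeR, other count filters, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), each library left out in turn, the replicate number as a block, counts summed over clusters, libraries thinned to the smallest total, library totals in place of TMM, and removal of the trend with contig length.

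The procedure was tested on simulated counts for 25353 contigs in the layout of the comparison of TnBP with control. Counts were drawn from the control means, the 6 library sizes multiplied by their TMM factors, and the fitted trend of dispersion with abundance. Of 100 contigs changed 4-fold, edgeR recovered 85%, and of 100 changed 2-fold it recovered 40%. In each set of 100, 87 passed the count filter and were tested. It made 7 false calls among 21909 unchanged contigs. Only 200 contigs were changed, as many up as down, without the shift in scaling seen between the real groups. Recovery and false calls may therefore differ in the real comparison, where many more contigs were called. In the same simulation DESeq2 recovered 110 and limma 98 of the 200 changed contigs, with 2 false calls each. The cluster shuffle was tested on 8089 simulated contigs. Random directions gave 1877 clusters with both directions against a shuffled mean of 1854 (two-sided permutation test, p = 0.358), and directions shared within clusters gave 0 against a shuffled mean of 1853. Figures were drawn with matplotlib 3.10.9.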

Results

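RNA was sequenced from the intestine of Eisenia fetida, a compost-dwelling earthworm used as a test species in soil toxicology. Adult worms were kept for 14 days in artificial soil as a control group or with 10 mg/kg of tri-n-butyl phosphate (TnBP), an organophosphate ester used as a flame retardant, plasticizer and solvent. Each group had 3 libraries, and each library pooled the intestines of 3 worms. The control libraries held 8435554 to 9099412 expected counts and the TnBP libraries 9494666 to 9643939. In all, 55641 assembled contigs had a value in some library and 35181 had one in all 6 libraries. Of these contigs, 8089 belonged to 3639 clusters and 47552 were single unigenes. The files give identifiers without gene names, so the contigs are described by abundance, length, cluster and presence, and no pathway is reported.

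The exposed intestines yielded more contigs, and their counts were spread over more of them. At least 1 count was found for 44322 ± 758 contigs in control libraries and for 50492 ± 530 in TnBP libraries (SD, n = 3), with all 3 TnBP libraries above all 3 control libraries (exact permutation test, p = 0.1, the smallest possible). With all libraries thinned to the smallest total, the numbers were 44072 ± 504 and 49900 ± 522. An FPKM of at least 1 was reached by 31641 ± 707 and 41244 ± 899 contigs, a difference of 9603 against 6171 at 1 count. The 10 most abundant contigs of each library took 43.1% ± 1.04 of the counts in controls and 29.5% ± 0.386 after TnBP (SD, n = 3). The 100 most abundant took 71.4% ± 1.01 and 57.5% ± 0.653. Both shares differed in the same way between all control and all TnBP libraries, at an exact permutation p of 0.1. Thinning evens out the totals but not these shares, which left more counts for the other contigs after TnBP. The larger number of contigs may follow from the lower shares, which was not tested. A single contig of 861 bases made up 8.98% ± 0.557 of control counts and 4.32% ± 0.138 of TnBP counts.

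**Figure D1:**
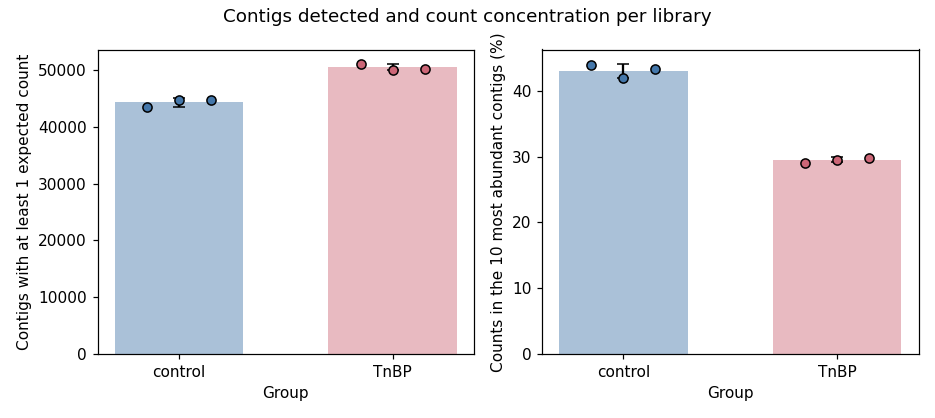
Number of contigs with at least 1 expected count (left) and percentage of counts in the 10 most abundant contigs (right), for 3 control and 3 TnBP libraries. Points are libraries, bars are means and error bars are SDs. TnBP libraries average 50492 contigs against 44322 in controls, and their 10 most abundant contigs hold 29.5% of counts against 43.1%.

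Libraries separated by treatment across the tested contigs. Pearson correlations of log2 CPM were 0.93 to 0.94 among control libraries and 0.96 to 0.97 among TnBP libraries, against 0.70 to 0.72 between groups. These correlations are across contigs, which are not independent replicates. The first principal component held 78.8% of the variance, and control and TnBP libraries lay at opposite ends of it. The coefficient of variation between pools, beyond counting noise, was 18.7% in controls and 13.5% after TnBP. Above 64 CPM, over 1084 contigs, it was 11.9% and 9.80%, and the difference between groups was not tested.

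TnBP was compared with control to ask which intestinal transcripts differed after exposure. Of 25353 contigs tested, 6110 were higher and 6211 lower after TnBP, together 48.6% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was called for 4282 higher and 4314 lower contigs. At 4-fold or more the numbers were 2065 higher and 1473 lower. The groups did not overlap for 57.7% of tested contigs, where chance gives 10%. The balance of directions rests on the TMM scaling, since library totals alone gave 13733 higher and 2831 lower contigs, and 10080 and 1824 at 2-fold or more. Limma on log2(FPKM + 1) gave 17387 higher and 3308 lower, and 11142 and 2066 at 2-fold or more, and a filter at 5 CPM gave 3624 and 3619, and 2016 and 2102. Leaving out any 1 library kept between 84.6% and 87.3% of the calls in the same direction, and 0 calls reversed. Fewer were kept by DESeq2 (74.0%, 0 reversed), library totals (72.6%, 163 reversed) and limma on log2(FPKM + 1) (71.3%, 105 reversed).

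**Figure D2:**
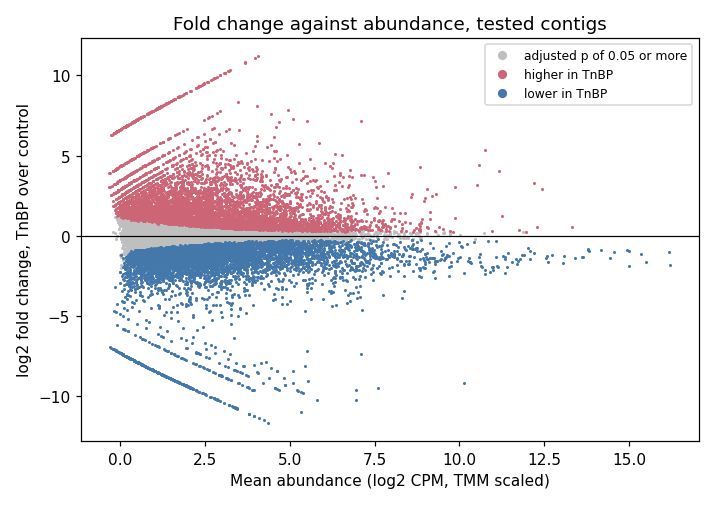
Log2 fold change of TnBP over control against mean abundance in log2 CPM for the 25353 tested contigs. Red and blue points are contigs called higher (6110) and lower (6211), grey points were not called, and the diagonal bands at the outer edges come from contigs with few or 0 counts in 1 group, whose fitted change depends on the prior count. The 10 most abundant contigs, at the right end, lie below 0, and 7 of them were called lower under library totals too.

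The most abundant intestinal transcripts fell relative to the rest. All 10 contigs with the largest mean share of counts were lower after TnBP, with log2 fold changes from -1.90 to -0.88 and standard errors of 0.085 to 0.13. Their largest adjusted p was 3.6e-05 (edgeR). Under library totals 7 of these 10 were called lower and 0 higher. Among the next 90 contigs by abundance, 63 were lower and 18 higher, and under library totals 51 were lower and 33 higher. Of the 900 contigs after rank 100, 308 were higher and 401 lower, and under library totals the balance turned, with 545 higher and 249 lower. Of the 4000 contigs after rank 1000, 1425 were higher and 1277 lower, and under library totals 2776 were higher and 575 lower. The 4314 contigs at least 2-fold lower took 65.2% ± 0.30 of control counts and 39.4% ± 0.615 of TnBP counts (SD, n = 3). The 4282 contigs at least 2-fold higher took 1.73% ± 0.0610 and 14.0% ± 0.223. Both sets were chosen for their change, so these shares describe its size in library totals and do not test it. The sets were chosen on TMM-scaled changes, which lie lower than changes in library totals by a log2 ratio of about 0.78. Against the TMM-scaled changes, the fall in share is therefore too small and the rise too large.

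Among contigs with reads in every library, the steepest rises were in 1 cluster. CL3240.Contig2_Eisenia_Fetida, 1231 bases long, rose from 1.87 ± 0.760 CPM to 268 ± 50.4 CPM (SD, n = 3), a log2 fold change of 7.17 ± 0.23 (SE, edgeR adjusted p = 3.9e-09). Its control libraries held 9.46 to 17 expected counts and its TnBP libraries 2685 to 3642. CL3240.Contig1_Eisenia_Fetida, a shorter contig, rose from 0.616 ± 0.447 to 87.2 ± 21.0 CPM, a log2 fold change of 7.16 ± 0.32 (edgeR adjusted p = 1.9e-08). The pair shares a cluster, and RSEM can divide reads between members, so the separate values are uncertain. CL1817.Contig1_Eisenia_Fetida, 864 bases long, fell from 253 ± 26.6 CPM to 0.189 ± 0.187 CPM, a log2 fold change of -10.29 ± 0.25 (edgeR adjusted p = 9.3e-10). Its TnBP libraries held 1, 1 and 5.17 expected counts, so the size of the change rests on few reads. Unigene32747_Eisenia_Fetida, 777 bases long, fell from 2237 ± 287 CPM to 3.74 ± 5.43 CPM, a log2 fold change of -9.22 ± 0.66 (edgeR adjusted p = 6.1e-07). Its TnBP libraries held 7, 8 and 124 expected counts, and without TnBP replicate 3 its log2 fold change was -11.83. Without that library CL1817.Contig1_Eisenia_Fetida stood at -11.39, and without control replicate 1 CL3240.Contig1_Eisenia_Fetida stood at 7.85. Lack of overlap between groups was a condition for naming these contigs. All 4 kept their direction and call under each of the 17 alternatives computed for them. Over these, their log2 fold changes ran from 6.93 to 7.95, 6.78 to 8.18, -11.39 to -7.45 and -11.83 to -8.43, in the order above.

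Fold changes differed with contig length. Of 2695 contigs over 2000 bases, 1169 were higher and 576 lower, with a median log2 fold change of 0.29; under library totals 2041 were higher and 239 lower, with a median of 1.08. Of 2746 contigs of up to 300 bases, 362 were higher and 1058 lower, with a median of -0.50; under library totals the balance turned, with 840 higher and 619 lower and a median of 0.27. Classes in between had medians of -0.22 up to 500 bases, 0.03 up to 1000 and 0.21 up to 2000, which were 0.55, 0.80 and 0.98 under library totals. Within each library, the median log2 CPM of contigs over 2000 bases exceeded that of contigs up to 300 bases by 2.75 ± 0.077 in controls and by 3.64 ± 0.055 after TnBP (SD, n = 3, exact permutation test, p = 0.1, the smallest possible). The Spearman correlation of length and fold change across contigs, which are not independent replicates, was 0.23. With the length trend removed, 11991 contigs were called, and 88.2% of the original calls were kept.

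**Figure D3:**
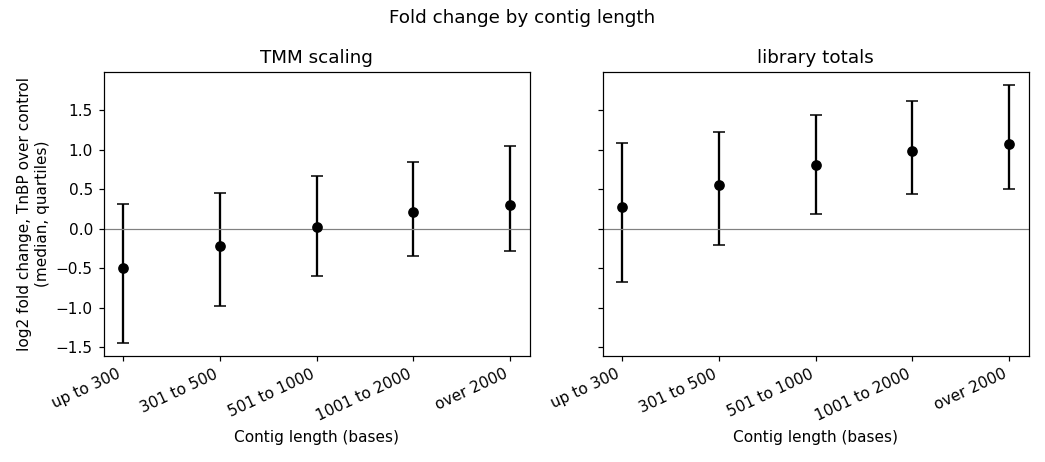
Log2 fold change of TnBP over control by contig length in bases, with TMM scaling (left) and with library totals (right). Points are medians and bars span the quartiles over contigs. Medians go from -0.50 to 0.29 between the shortest and the longest class with TMM scaling, and from 0.27 to 1.08 with library totals.

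Some transcripts were found in 1 group only. In controls 277 contigs had at least 10 counts in all 3 libraries and under 1 in every TnBP library, and 218 contigs showed the reverse. The limits were set on counts without scaling, and the mean TMM factor was 0.763 in controls and 1.31 after TnBP. A given count thus stands for a lower TMM-scaled CPM in TnBP libraries, and the 2 sets were taken at unlike limits on that scale. Their median counts per library were 33.3 and 31.1, and 30 control-only and 33 TnBP-only contigs averaged at least 100. Control-only contigs summed to 0.150% ± 0.00523 of control counts and TnBP-only contigs to 0.12% ± 0.00334 of TnBP counts (SD, n = 3). Control-only contigs had a median length of 331 bases, TnBP-only contigs 741.5 and all tested contigs 727.

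Contigs of the same cluster mostly changed in the same direction. Of 821 clusters with several called members, 585 had members of 1 direction and 236, or 28.8%, had members called in both. Shuffled directions gave 451 clusters with both on average and 400 to 495 over 1000 shuffles, so the observed number was lower than with shuffled directions (p = 0.002, two-sided permutation test, the smallest possible). The shuffle treats members as independent, whereas RSEM can divide reads between members of a cluster. Linked counts and shared regulation cannot be told apart here. Among tested cluster contigs 1791 were higher and 1264 lower, against 4319 higher and 4947 lower single unigenes. Under library totals both kinds leaned towards higher, with 3234 higher and 599 lower cluster contigs and 10499 higher and 2232 lower single unigenes.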

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

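Of the alternatives, 3 were chosen after the data had been seen: library totals in place of TMM, removal of the length trend, and FPKM correlations. Called contigs stayed within 1.5 times of 12321 with DESeq2 size factors (12334), DESeq2 itself (10094), no count filter (14182), cluster sums (12096), thinning (12070), the length trend removed (11991), library totals (16564), and any library left out (11114 to 11893). The labels number the libraries 1 to 3 in both groups, but deviations of same-numbered libraries from their group means had correlations of -0.003, 0.045 and -0.016, so the numbers were not read as pairs, and not every library correlated best with its own number. With the replicate block 11253 contigs were called, and the block moved no count by over 1.5 times. A filter at 5 CPM in 3 libraries left 11073 contigs to test and called 7243, of which 3624 were higher and 3619 lower; at 2-fold it called 4118, of which 2016 were higher and 2102 lower. FPKM values and library totals carry no TMM factor, and their median log2 fold changes were 0.49 to 0.84; the FPKM fits also tested more contigs, 40444 or 55641, and other causes were not tested. Among the original calls, 95 to 109 were called in the opposite direction in the FPKM fits and 163 under library totals. Called or not, 1021 or 1022 changed sign in the FPKM fits and 1028 under library totals. A similar number of calls did not mean the same calls: DESeq2 kept 74.0% of the original ones in the same direction, library totals 72.6% and the FPKM fits 70.4% to 71.3%. Limma on log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered log2(FPKM + 1) called 20695, 18928 and 21487 contigs, with 17387, 15836 and 18236 higher and 3308, 3092 and 3251 lower. At 2-fold these fits called 13208, 15003 and 13744, with 11142, 12799 and 11665 higher and 2066, 2204 and 2079 lower. Library totals gave 13733 higher and 2831 lower, and 10080 and 1824 at 2-fold. The excess of contigs detected after TnBP was 7129 at 10 counts and 9603 at an FPKM of 1, against 6171 at 1 count. The share of the 10 most abundant contigs fell by 14.4 points in FPKM and fell by 13.6 in counts, and the mean correlation between groups was 0.669 in log2(FPKM + 1), against 0.711; for these the cause was not tested. With calls of at least 2-fold, 112 of 527 clusters (21.2%) had both directions, against 236 of 821 (28.8%); the cause of the lower share was not tested. Contigs found in 1 group only numbered 276 and 215 with limits of 0 and 5 counts, against 277 and 218. Gene list alternatives were not run, because no identifier matched a list. Of 100 contigs changed 2-fold in the simulation, 87 passed the count filter and 40 were recovered. Which of depth, number of libraries and spread between pools limits recovery was not tested. The simulation changed only 200 contigs and made the TnBP libraries deeper than the real ones, so recovery in the real comparison may differ.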

Other observations

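The summed shares, the comparison of cluster membership, the length-trend removal, the test on library totals and the removal of the 10 most abundant contigs reported here were chosen after the data had been seen, and the 3 patterns weighed were noticed in these data, with the other tests of their explanations set down before the results of those tests were seen. The sets of contigs with the steepest changes were chosen for their change, so their shares describe its size and do not test it. The 1044 contigs called at least 8-fold higher after TnBP made up 0.221% ± 0.00873 of control counts and 5.13% ± 0.184 of TnBP counts (SD, n = 3). The 675 contigs called at least 8-fold lower made up 1.32% ± 0.0260 and 0.0938% ± 0.0198. Of the former, 7 reached at least 0.1% of counts in a group, and of the latter 1 did. Contigs found in 1 group only also differed in kind: 18 of 277 control-only contigs belonged to clusters, against 111 of 218 TnBP-only contigs (50.9%) and 21.7% of all tested contigs. Control-only and TnBP-only contigs differed in this (two-sided Fisher's exact test across contigs, which are not independent, p = 2.3e-30). The test counts several members of 1 cluster apart. It takes no account of length, and the median lengths were 331 bases for control-only and 741.5 for TnBP-only contigs.

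The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many as 12321 called contigs. The other splits gave at most 0 calls with edgeR and at most 216 contigs at an unadjusted p under 0.05, against 13878 for the real split; DESeq2 was not run on them. For changes of at least 2-fold the real value was 8596 and the highest other 0, and for contigs found in 1 group only these were 495 and 0. Each of the other splits mixes control and TnBP libraries, so the difference between the groups enters their spread and hardly any call could arise. The contrast with the real split therefore decides nothing about chance.

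The TMM factors averaged 0.763 ± 0.0216 in controls and 1.31 ± 0.0393 after TnBP (SD, n = 3), so the typical contig was higher in TnBP by a log2 ratio of 0.79 in library totals. Thinning all libraries to the smallest total left 0.78 and decides nothing, because the ratio is already scaled to library totals; the totals themselves argue against unequal depth, as they differed by a log2 ratio of 0.12, and by at most 0.19 between any pair of libraries. Leaving the 10 most abundant contigs out of the totals lowered the ratio to 0.48, and leaving out the 100 most abundant lowered it to 0.23, so the abundant contigs may carry part of the gap, with the 10 most abundant alone leaving most of it; what remains without the 100 lies between the bounds set in advance for and against them as the whole cause. Whether the abundant transcripts fell or the rest rose cannot be told apart, because the counts are relative and the tables hold no external standard. An effect of exposure on the abundant transcripts stays open and was not tested.

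Longer contigs were higher and shorter ones lower after TnBP, relative to the TMM shift; under library totals the medians of all length classes lay above 0, and the shortest stayed lowest. Abundance in counts was argued against as the reason: the gap in median log2 fold change between contigs over 1000 bases and those up to 500 bases was 0.52 over all contigs and at least 0.77 within each abundance quartile. Counts grow with length: the lowest quartile held 441 of the longer and 3830 of the shorter contigs, the highest 4504 and 476. Abundance per base was not examined and stays open as a reason. A dependence of read recovery on length, as RNA integrity or fragment selection could give, went with a test that could have failed: in 58.2% of 665 clusters (exact 95% interval 54.3 to 62.0) the longest contig had a higher fold change than the shortest, where it was at least 2 times as long. The median difference within these clusters was only 0.22 in log2 fold change. Other causes linked to contig length could give the same direction, so the test does not single out read recovery. The gap with length separates the groups and not the libraries within a group, so sample handling and exposure stay open together. Removing the trend gave 11991 calls and kept 88.2% of the original ones, so the average trend with length does not account for most of them. Only 1 smooth trend per library was removed, so recovery that differs between contigs of similar length was not examined.

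Contigs present in 1 group only may be sequence variants that differ between the worms of the groups, transcripts of cells or organisms present in 1 group, or strongly regulated genes. If variants replaced each other, the other contigs of a cluster would move the opposite way. Their median log2 change, signed to be positive when they moved with the contig, was -0.58 for 12 control-only contigs (95% bootstrap interval -5.19 to 3.89) and 0.039 for 96 TnBP-only contigs (-0.25 to 0.69), which leaves this open, and single unigenes could not be examined. A source present in 1 group could vary in amount between pools: the spread of the set's median between libraries exceeded that of 69.7% of matched random sets for control-only and 71.5% for TnBP-only contigs, between the bounds set in advance. These explanations cannot be told apart without sequences or gene names, and exposure itself stays open.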
